A study of Rattus norvegicus with 10 samples.

How the data were processed

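Total RNA from cells named A7r5 in the labels was labelled with biotin and hybridised to single-colour Affymetrix rat arrays, per the labels' protocols. The 10 arrays formed 5 groups of 2 by the transfected construct that each label names: empty vector, wild-type human BMPR2, and the CD, KD and ED mutants of BMPR2. The table deposited by the authors holds log2 probe set summaries made with RMA, per the submitters' processing notes; the RMA version and whether all arrays were normalized together are not given in the sources used here. RMA subtracts background, equalises the distributions of arrays and summarises the probes of a probe set, and it compresses differences at low signal. Values ran from about 2 to just under 15 and none was missing. The median was 5.32 to 5.36 on 8 arrays and 4.94 and 4.95 on the KD mutant arrays, and the SD across probe sets was 1.89 to 1.91 and 2.26 to 2.27, so the distributions of the KD mutant arrays differed from the rest. No detection calls or scanner intensities were used here, so a probe set cannot be called present or absent, and the number of arrays limits the precision.

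Of 31099 probe sets, 57 Affymetrix controls were left out of all comparisons between groups. Names came from the platform annotation given: 20826 probe sets have 1 gene, 436 have several and 9780 have none there. Symbols of 20758 probe sets were updated through Entrez identifiers with the RefSeq gene table of the rat assembly GRCr8, which was used for names and not for coordinates. No gene was named from a probe set with several genes. A probe set was tested when it reached the 40th percentile of all values, log2 4.82, on at least 2 of the 10 arrays, which left 22502.

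The deposited values were fitted with limma 3.58.1 in R 4.3.3 (lmFit on all 10 arrays with 5 group means, contrasts, eBayes), so that the groups shared 1 estimate of the spread with 5 residual degrees of freedom and 11.4 after moderation. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets of each comparison, and an adjusted p under 0.05 counted as changed. All adjusted p-values of genes come from this limma fit and are two-sided, and SE is the moderated standard error of the log2 difference. The SDs are over the 2 arrays of a group, or over all 8 where so stated. Each group was compared with each other, and the mean of the 3 mutants with wild type. Gene lists, 31 in number and holding 920 members, were written before the data were examined, and covered BMP and TGF-beta signalling, smooth muscle, matrix, growth, inflammation, stress, metabolism and other cell types. For them each gene was represented by its probe set with the highest mean (12040 genes), and a list needed 5 measured genes. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 31 lists.

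The genes named were set by a rule fixed before the data were examined. The rat Bmpr2 probe sets come first. For wild type against empty vector and each mutant against wild type, the rule takes the 10 largest rises and 10 largest falls among changed named genes, with 1 probe set per gene, whose arrays do not overlap between groups, so probe sets outside it can differ by more. For the other comparisons it takes 5 and 5, and from each list up to 4 members with the lowest adjusted p. Genes outside this rule, such as those used to describe the KD mutant arrays (Vim, Eef1a1, Pgk1, Acta2), were chosen after their values were seen.

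The model was tested on simulated data made from the real probe set means and spreads. In a simulated comparison of CD mutant with wild type over 22502 probe sets, 45.5% of 66 probe sets changed by 0.5 on the log2 scale were recovered and 100% of 67 changed by 1, with 8 false calls. A further 67, changed by 2, were planted in the same data, and all were recovered. Recovery with fewer true changes was not simulated. In the list step over 12040 genes, 3 of 3 lists of 25 genes shifted by 0.2 were recovered and 0 of 20 unshifted lists were called. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.236. False calls among correlated genes at the preset correlation were thus not tested. Overlaps of comparisons with the same controls were set beside 100 simulations of unchanged groups. Labels give replicate numbers 1 and 2 in every group; whether they pair samples was checked from the correlation of deviations from the group means.

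The alternatives set before the data were examined were no filter, a filter at the 60th percentile, quantile normalization, centring of each array on its median, eBayes with an intensity trend and robust variance, a replicate block, a 1.5-fold minimum, an adjusted p under 0.01, genes in place of probe sets, only the arrays of the groups compared, leaving out each array in turn, and, for lists, camera with an estimated correlation, fry, and the mean of all probe sets of a gene. A fit and filter without the 2 KD mutant arrays was added after the data were seen.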

Results

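Gene expression was measured in cells labelled as A7r5, a smooth muscle line derived from embryonic rat aorta, stably transfected with human BMPR2 or with an empty vector. BMPR2 is a type II receptor for bone morphogenetic proteins, and its germline mutations cause heritable pulmonary arterial hypertension. The 5 groups were labelled as cells with empty vector, with wild-type BMPR2, and with BMPR2 mutated in the cytoplasmic tail (CD mutant), in the kinase domain (KD mutant) or in the extracellular ligand-binding domain (ED mutant). Each group had 2 arrays, from cells at about 50% confluence in 10% serum. The comparisons asked how receptor expression changed transcription in cells labelled as vascular smooth muscle, how each class of mutation differed from the wild-type receptor, and whether the 3 classes shared changes. All values are log2 RMA summaries as deposited by the authors, 22502 probe sets passed the filter on dim probe sets, and "changed" means an adjusted p under 0.05 in limma. Where a group mean lay below the filter level of log2 4.82, the size of the difference and its rank were not measured exactly. The labels do not say that the 2 arrays of a group came from separate cultures, so p-values measured the spread between these arrays, which may be technical, and the number of arrays limited the precision.

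The rat Bmpr2 gene was read first. Its 2 probe sets are annotated to the rat gene. Whether they also bind the human transcript was not tested, as no probe sequences were used, so they do not check the human transgene. The brighter one stood at 6.68 ± 0.023 (SD, n = 2) with empty vector, 7.08 ± 0.19 with wild-type BMPR2, 7.03 ± 0.26 in the CD mutant and 6.9 ± 0.15 in the ED mutant, and the CD and ED mutants did not pass the test against wild type (adjusted p = 1 and 0.838). Wild type stood 0.403 above empty vector by this probe set, without passing the test (adjusted p = 0.593 in limma). On the arrays labelled KD mutant this probe set stood at 8.51 ± 0.012, which was 1.43 above wild type (adjusted p = 8.82e-07). The dimmer probe set of the same gene went the opposite way there, from 5.31 ± 0.022 in wild type to 3.85 ± 0.031, a fall by 1.46 (adjusted p = 1.19e-07).

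The 2 arrays labelled KD mutant stood apart from the other 8 over the whole transcriptome. Across probe sets, their Pearson correlation with the other 8 arrays was 0.712 to 0.721, against 0.992 to 0.996 among those 8 and 0.993 between the KD mutant pair. Several genes of smooth muscle and fibroblasts, chosen after their values were seen, were brighter on the KD mutant arrays than on the rest. Col1a2, a fibrillar collagen chain, averaged 13.62 ± 0.23 (SD, n = 2) against 3.88 ± 0.21 over the other 8, Tagln, an actin-binding protein of smooth muscle, 11.33 ± 0.25 against 4.98 ± 0.11, and Acta2, smooth muscle actin, 9.38 ± 0.47 against 6.26 ± 0.09. Myh11, the smooth muscle myosin heavy chain, did not follow, at 6.95 ± 0.05 against 6.79 ± 0.19 by its brighter probe set. Of 23 contractile genes, 15 lay above percentile 80 on the KD mutant arrays, and 8 did on the other 8 arrays. The epithelial genes Cdh1, which encodes E-cadherin, and Krt18, a keratin, went the other way, with 5.87 ± 0.18 against 9.71 ± 0.39 and 9.31 ± 0.04 against 11.47 ± 0.21, while another keratin gene, Krt8, stood at 8.1 ± 0.23 against 8.53 ± 0.28. COX1, a mitochondrially encoded subunit of cytochrome oxidase, averaged 14.16 ± 0.11 on the KD mutant arrays and 4.84 ± 0.37 on the others. Of the glycolytic gene Pgk1, one probe set was bright on both sets of arrays, at 12.76 ± 0.02 on the KD mutant arrays and 13.33 ± 0.07 on the others, whereas another read 13.23 ± 0.01 and 3.34 ± 0.11. Levels of Vim, at 13.25 against 12.74, and of the elongation factor gene Eef1a1, at 14.21 against 14.26 by its brighter probe set, lay close together. Control transcripts moved with this split: the poly-A controls averaged 6.82 on the KD mutant arrays against 8.04 on the others, the hybridization controls 10.19 against 11.05, and the bioB control 7.75 against 9.07. The comparisons are therefore given as measured on the arrays that carry each label. Those without the KD mutant rest on the 8 arrays on which Col1a2, Tagln and COX1 were dim and Cdh1 and Krt18 bright.

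**Figure D1:**
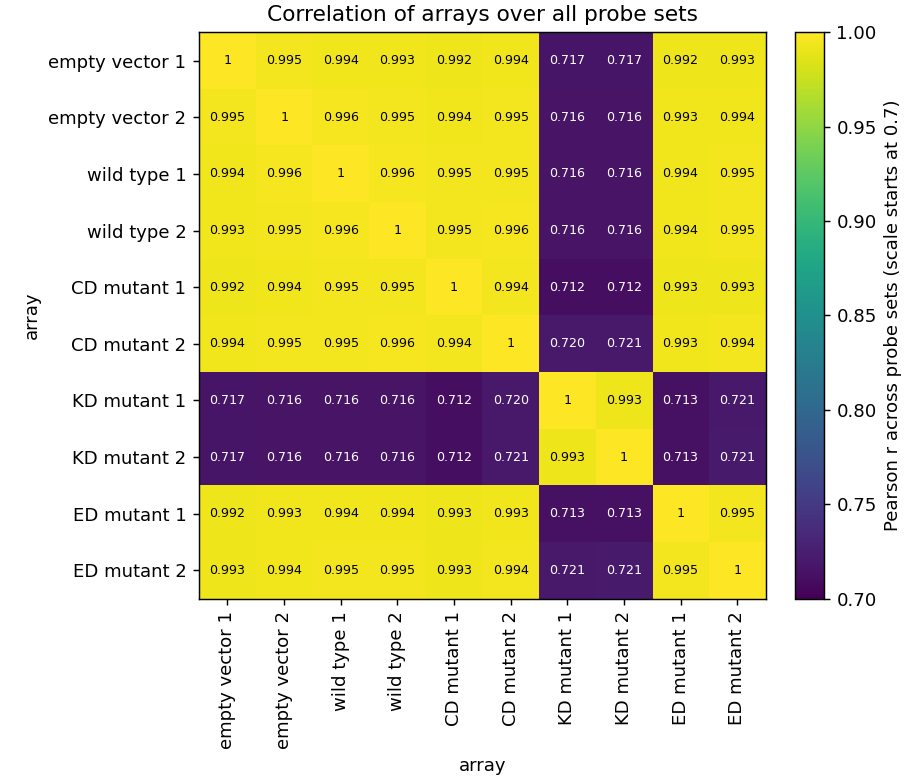
Pearson correlation between each pair of the 10 arrays over all probe sets, with arrays on both axes and the colour scale starting at 0.7. The 2 KD mutant arrays correlate with each other at 0.993 and with the other 8 arrays at 0.712 to 0.721.

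**Figure D2:**
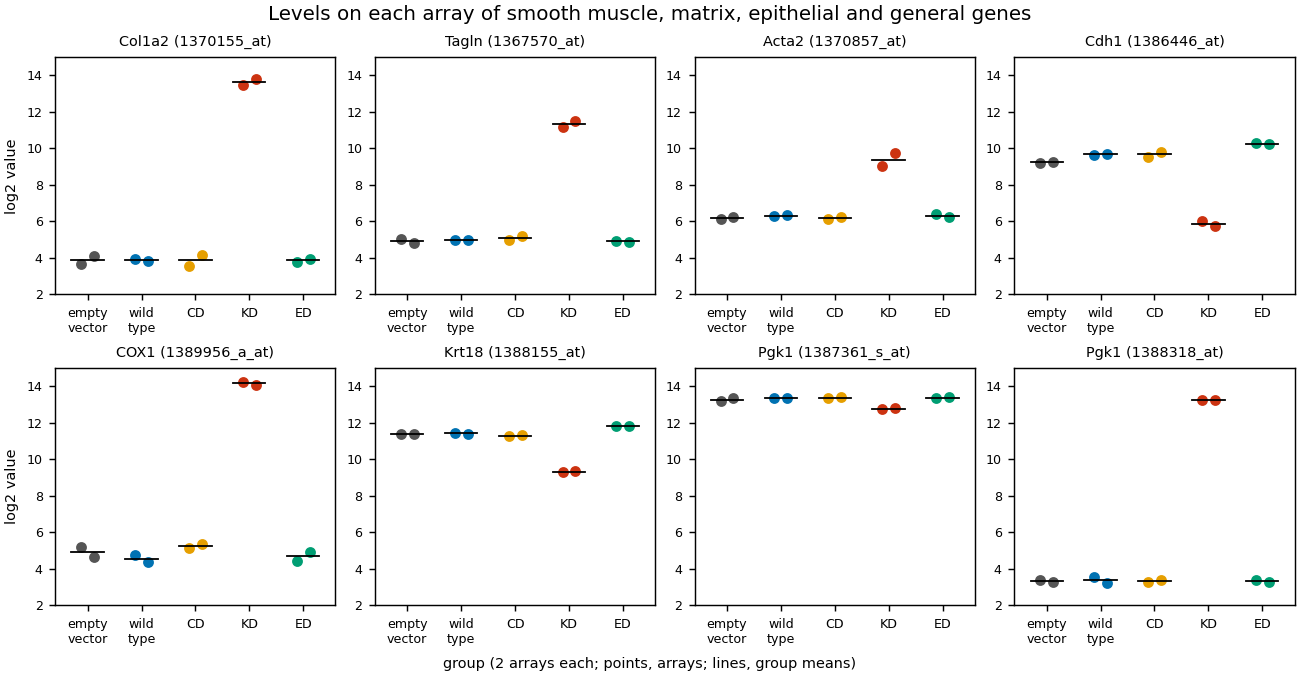
Log2 values of 8 probe sets on each of the 10 arrays by group, with points for arrays and lines for group means. Col1a2, Tagln, Acta2 and COX1 are brighter on the 2 KD mutant arrays, Cdh1 and Krt18 are dimmer, and the 2 probe sets shown for Pgk1 disagree (13.23 against 3.34 by one, 12.76 against 13.33 by the other).

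The effect of the wild-type receptor was read against empty vector. Ccl2, which encodes a chemokine that attracts monocytes, fell from 8.86 ± 0.024 (SD, n = 2) to 7.44 ± 0.088, by 1.42 on the log2 scale or 2.67-fold (SE 0.104, adjusted p = 0.000464). Ccl20, the chemokine ligand of the receptor CCR6, fell from 8.13 ± 0.042 to 7.31 ± 0.095, a 1.76-fold difference (adjusted p = 0.0486). Mia2, which takes part in export of large cargo from the endoplasmic reticulum, rose from just below the filter level, 4.81 ± 0.067, to 5.72 ± 0.15 (adjusted p = 0.0486). These values, and those of the CD and ED mutants, come from the 8 arrays with low Tagln and Col1a2 and high Cdh1. These were the 3 probe sets that changed, 1 up and 2 down, and 1471 had an unadjusted p under 0.05 where 1125 are expected by chance. Among the target genes of BMP signalling, 0 of 17 measured rose or fell, and 3 fell when adjusted over the list alone. The members with the lowest p were the inhibitors of differentiation Id3, at -0.82 (adjusted p = 0.126), Id1, at -0.45 (adjusted p = 0.345), and Id2, at -0.40 (adjusted p = 0.454). The list's median change was 0.02, its mean -0.046, and camera gave no shift (adjusted p = 0.782). In the chemokine, cytokine and NF-kB list, 2 of 28 members fell, Ccl2 and Ccl20, with 2 also when adjusted over the list alone. No list of the 31 shifted as a whole by camera, the lowest adjusted p being 0.129, while 4 had an unadjusted p under 0.05 and fry called 1, the p53 and growth arrest list (adjusted p = 0.00233 for a net fall of its members). In that list 0 of 20 members passed over all probe sets and 2 fell when adjusted over the list alone. Leaving out any 1 of the 4 arrays left 1 changed probe set, as did fitting only these 4 arrays.

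The CD mutant could not be separated from wild-type BMPR2. In limma 0 probe sets changed, and 784 had an unadjusted p under 0.05, fewer than the 1125 expected by chance. That shortfall depended on the KD mutant arrays. With them left out of filter and fit, a setting added after the data were seen, 0 changed and 1019 of 19534 had an unadjusted p under 0.05. In simulated data for this comparison, 30 of 66 probe sets changed by 0.5 on the log2 scale were recovered, as were 67 of 67 changed by 1. These were planted together with 67 changed by 2, and many true changes ease the adjusted threshold. A few changes of 2-fold could therefore be missed here, and smaller ones more so. In wild type against empty vector, Slc5a11 differed by 1.035 without passing the test (adjusted p = 0.126 in limma). Of the 31 lists 0 shifted by camera, 5 had an unadjusted p under 0.05, and fry called 0. The BMP target list had 0 of 17 members changed, also when adjusted over the list alone, with a median change of -0.047 (adjusted p = 0.141). Members of the smooth muscle contractile list had a median of -0.005 with 0 of 23 changed, and those of the extracellular matrix list 0.015 with 0 of 35 changed; both counts were also 0 when adjusted over the list alone.

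Most genes that differed between the ED mutant and wild-type BMPR2 were higher in the mutant. Acta1, the skeletal muscle actin, rose from 7.02 ± 0.3 (SD, n = 2) to 8.39 ± 0.0068, or 2.59-fold (SE 0.158 on the log2 scale, adjusted p = 0.0229). Slc5a11, a sodium-dependent inositol transporter, rose 2.16-fold to 8.35 ± 0.12 (adjusted p = 0.0295), Hpx, the haem-binding plasma protein hemopexin, 2.03-fold to 8.73 ± 0.26 (adjusted p = 0.0236), and Ctsh, a lysosomal protease, 2-fold to 8.44 ± 0.12 (adjusted p = 0.0229). The other large rises were Slc7a7, a subunit of a cationic amino acid transporter, from 4.35 in wild type, below the filter level, to 5.31, Lurap1l at 1.94-fold, Crip1 at 1.84-fold, Coq3, an enzyme of ubiquinone synthesis, at 1.83-fold, Lgals4, a galectin, at 1.8-fold, and Flrt3 at 1.77-fold, with adjusted p from 0.0239 to 0.0445. Fbln2, the matrix protein fibulin 2, fell from 7.52 ± 0.12 to 6.75 ± 0.052, a 1.7-fold difference (adjusted p = 0.0245). Ccdc80, Adprm and Tmem223 also fell, with log2 changes of -0.735, -0.698 and -0.669 and adjusted p from 0.0236 to 0.0445. For Adprm, the ED mutant mean of 8.67 lay near the 8.82 of empty vector, with wild type higher at 9.37. In all, 31 probe sets were higher and 6 lower, which named 25 genes higher and 4 lower. All 4 arrays are among the 8 with low Tagln and Col1a2 and high Cdh1.

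Among the lists, Klf4, a transcription factor, rose by 0.74 (adjusted p = 0.0236) and was the 1 of 24 immediate early genes to change, although 6 rose and 2 fell when adjusted over the list alone. Ccl20 rose by 0.69 (adjusted p = 0.03), the 1 of 28 chemokine and cytokine genes to change, also over the list alone. Its mean of 8 in the ED mutant lay near the 8.13 of empty vector, with wild type lower at 7.31. Fbln2 was the 1 of 35 extracellular matrix genes to fall, and 3 fell when adjusted over the list alone. Acta1 was the 1 of 25 skeletal muscle genes to change, and over the list alone Acta1 rose and Myh3, the embryonic myosin heavy chain, fell (log2 change -0.532, adjusted p = 0.172 over all probe sets). The epithelial list came closest to a shift, with a median of 0.21 over 13 genes (camera adjusted p = 0.0598, and 0.668 with an estimated correlation). None of its members passed over all probe sets, and 5 rose and 1 fell when adjusted over the list alone; Cdh1 stood 0.58 higher (adjusted p = 0.151) and Krt19 0.54 higher (adjusted p = 0.112). The BMP target list had 0 of 17 members changed by either adjustment, a median of -0.02, a mean of 0.002 and a camera adjusted p of 0.943. Of the 31 lists 0 shifted by camera and 5 had an unadjusted p under 0.05. Fry, which tests for a net change of the members, called 2, the epithelial list (adjusted p = 0.00399) and the p53 and growth arrest list (adjusted p = 0.0226), both up; the latter had a median of 0.116 and 0 of 20 members changed by either adjustment. The 37 changed probe sets became 1 without wild type replicate 1 and 0 without wild type replicate 2 or either ED mutant replicate, as well as 0 when only these 4 arrays were fitted.

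**Figure D3:**
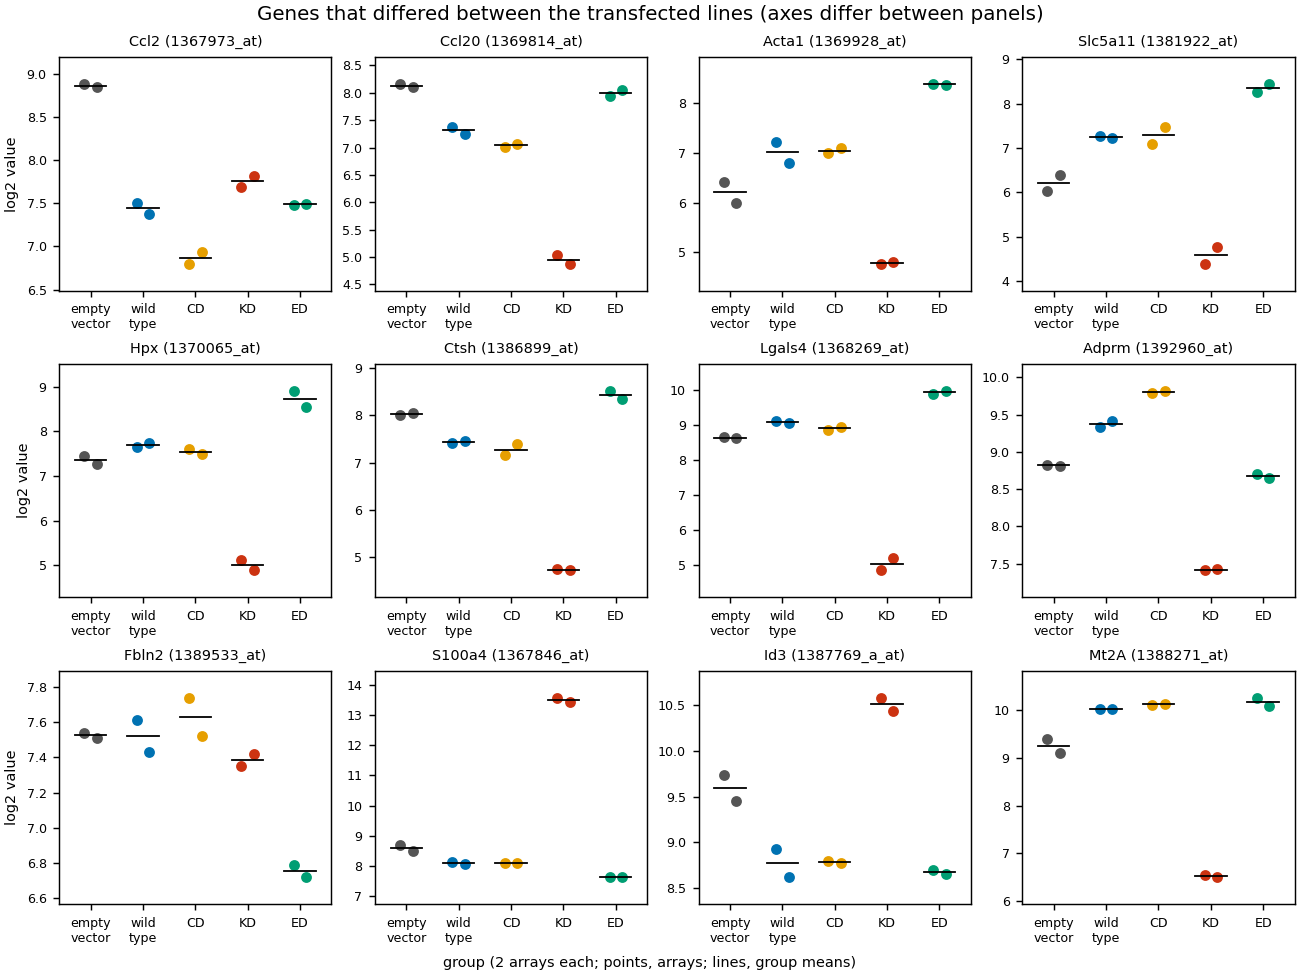
Log2 values of 12 genes on each of the 10 arrays by group, with points for arrays, lines for group means and a separate vertical axis for each gene. Ccl2 is highest with empty vector, at 8.86, and Acta1, Slc5a11, Hpx and Lgals4 are highest in the ED mutant, at 8.39, 8.35, 8.73 and 9.95.

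Against empty vector, some genes changed in both the CD and the ED mutant, and moved the same way with wild-type BMPR2. In the CD mutant Ccl2 fell 3.96-fold to 6.87 ± 0.098 (SD, n = 2; adjusted p = 1.16e-05), Ccl20 2.14-fold to 7.04 ± 0.04 (adjusted p = 0.00289), and Nrep, Slc17a1, a sodium-phosphate transporter of kidney, and Ctsh 1.95-, 1.79- and 1.69-fold. Slc5a11 rose 2.11-fold (adjusted p = 0.0397), Adprm 1.97-fold (adjusted p = 0.00289), Adarb1, an RNA-editing deaminase, 1.85-fold, the metallothionein gene Mt2A 1.83-fold, and Parp12 1.75-fold. In total 25 probe sets changed in the CD mutant, 12 up and 13 down. In the ED mutant 119 changed, 83 up and 36 down. Acta1 rose 4.54-fold (adjusted p = 0.000273), Slc5a11 4.42-fold (adjusted p = 0.000273), Fgb, the fibrinogen beta chain, 2.96-fold, Hpx 2.58-fold and Crip1 2.55-fold. Ccl2 fell 2.59-fold (adjusted p = 0.000273), Gja1, which encodes the gap junction protein connexin 43, 2.04-fold, S100a4, a calcium-binding protein, 1.93-fold, and Id3 from 9.59 ± 0.2 to 8.67 ± 0.036, or 1.9-fold (adjusted p = 0.0107). Bend5 also fell (adjusted p = 0.0308), between means of 4.73 ± 0.4 and 3.68 ± 0.12 that both lie below the filter level. Both mutants shared 8 probe sets, 5 up and 3 down, where independent lists would share 0.0443 up and 0.0208 down. Those values take no account of the shared empty vector arrays. Simulated unchanged groups against the same controls shared 0, but they held no differences to call. Neither is thus a reference for the overlap of lists of this length with shared controls. The shared named genes were Slc5a11, Parp12, Mt2A and Depp1, which rose, and Ccl2, Slc17a1 and Greb1l, which fell; Depp1 and Greb1l were named after their values were seen. Wild type against empty vector moved the same way in all 7, with log2 changes of 1.03 for Slc5a11, 0.78 for Mt2A, 0.66 for Depp1, 0.40 for Parp12, -1.42 for Ccl2, -0.76 for Slc17a1 and -0.47 for Greb1l, of which Ccl2 passed the test. Part of this overlap may come from the shared controls, which were too few to split. The covariance of the fold changes was 0.016 against 0.00884 simulated. With wild type in place of the other mutant, it was 0.0171 for CD and 0.0163 for ED. Poly-A control transcripts were also higher than with empty vector, by 0.66 in the CD mutant and 0.32 in the ED mutant, and the CD mutant's changes and the shared probe sets were not tested against them. The CD count was 1 without any 1 of its 4 arrays. The ED count was 19 and 37 without empty vector replicates 1 and 2, and 25 and 36 without ED mutant replicates 1 and 2.

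Set against each other, the ED and CD mutants differed in 79 probe sets, 55 higher and 24 lower in the ED mutant. Acta1 was 2.54-fold higher in the ED mutant (adjusted p = 0.00402), Flrt3, a membrane protein with leucine-rich repeats, 2.52-fold (adjusted p = 0.000808), Lurap1l 2.31-fold, Hpx 2.26-fold and Ctsh 2.24-fold. Lower in the ED mutant were Bend5, at 3.68, below the filter level, against 4.97, Adprm, 2.19-fold (adjusted p = 0.000808), Apln, which encodes the vasoactive peptide apelin, 2.07-fold (adjusted p = 0.00568), Lamb1, a laminin chain, 2.05-fold, and Myh3 2.03-fold (adjusted p = 0.00342). Leaving out CD mutant replicates 1 and 2 gave 18 and 31 probe sets, and leaving out ED mutant replicates 1 and 2 gave 16 and 12. Poly-A control transcripts averaged 8.45 in the CD mutant and 8.12 in the ED mutant, and the differences between these mutants were not tested against them.

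The arrays labelled KD mutant differed from wild type in 20166 probe sets, 7762 higher and 12404 lower (38.5% higher), and in 19996 after centring each array on its median, of which 9648 were higher (48.2%). The median probe set lay 0.556 below wild type in the deposited values, 0.491 below after quantile normalization and 0.161 below after centring each array on its median, and the changes given here are on the deposited scale, relative to that shift. By the deposited values, the rises that the rule takes, with 1 probe set per named gene, were Gpr15lg, by 9.87 on the log2 scale (SE 0.174, adjusted p = 7.71e-13), Col1a2 by 9.74, the mitochondrially encoded COX2 and COX1 by 9.70 and 9.62, the microfibril gene Mfap5 by 9.38, Serpinh1, a collagen chaperone, by 9.26, Grem1, a BMP antagonist, by 8.93, Calu by 8.53, the small heat shock protein gene Hspb1 by 8.39 and Sem1 by 8.05. All of these stood at 3.17 to 4.54 in wild type, below the filter level, so their sizes and order are those of compressed values. Among the 10 falls that the rule takes, Ppargc1a, a coactivator of mitochondrial biogenesis, went from 9.27 ± 0.00066 (SD, n = 2) to 4.14 ± 0.14, a log2 change of -5.14. The others had log2 changes of -5.07 for Chchd10, -5.02 for Id2, -4.78 for the retinol carrier gene Rbp4, -4.5 for Plpp3, -4.45 for Sorl1, -4.16 for Zfhx4, -4.055 for Lgals4, -3.97 for Agpat5 and -3.89 for Gphn, with adjusted p from 1.8e-12 to 1.9e-10. On the KD mutant arrays Ppargc1a, Rbp4 (3.9) and Zfhx4 (4.59) lay below the filter level, so the order of the falls was not measured exactly either.

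Among the lists, TGF-beta target genes lay furthest above wild type on the KD mutant arrays, with 14 of 16 up, 0 down and a median of 4.17. Examples were the collagen cross-linking enzyme Lox, up by 7.51, the matricellular gene Ccn2 by 7.27, the metalloproteinase inhibitor Timp1 by 6.79 and Postn by 6.04. Of 23 smooth muscle contractile genes 14 rose and 6 fell, with Tpm2 up by 6.47, Actg2 by 6.36, Tagln by 6.35 and Myl9 by 5.15. Of 35 extracellular matrix genes 22 rose and 8 fell, among them Col5a2, up by 8.02, and Col8a1, up by 5.66. Among matrix remodelling enzymes 18 of 24 rose and 5 fell, including Loxl1, up by 6.15, and Loxl2, up by 5.42. In the cell cycle list 21 of 35 rose and 9 fell, with the proliferation marker Mki67 up by 5.19 and Cdc20 changed by -3.69. Focal adhesion genes rose in 15 of 23 and fell in 4, with Cav1 up by 6.0 and Lpp at -1.95, and cholesterol synthesis genes rose in 14 of 19 and fell in 3, with Msmo1 up by 3.09 and Stard4 at -2.06. Of 13 epithelial genes 11 fell and 1 rose; Cdh1 changed by -3.81 and Krt19 by -3.27, while Krt7 rose by 4.78. Lox, Postn, Actg2, Col5a2, Loxl2 and Mki67 stood below the filter level in wild type. Counts adjusted over the list alone were the same for these 8 lists. By camera, 7 of the 8 shifted up and the epithelial list down (adjusted p from 2.38e-05 for TGF-beta targets to 0.0453), and 0 of them with an estimated correlation (adjusted p = 0.372 to 0.517 with an estimated correlation). After quantile normalization 4 lists remained shifted, the focal adhesion, cell cycle, cholesterol and epithelial lists losing the call (adjusted p = 0.101 to 0.357).

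BMP target genes moved both ways on the KD mutant arrays, with 3 of 17 up and 14 down by both adjustments. Grem1 and Bmper, which encode secreted BMP-binding proteins, were up by 8.93 and 6.26 from levels below the filter in wild type, Id2 changed by -5.02, and Gata6 by -2.74 to a level below the filter. The list's median was -1.37 and camera gave no shift (adjusted p = 0.138). Beside each of these groups stands the measured fact that probe sets of one gene often disagreed: of 2815 genes with 2 or more changed probe sets, 1150 had probe sets that went in opposite directions. That count takes changes of any size. Among 1122 genes with 2 or more brighter probe sets past 2-fold, 32.2% had opposite directions. Shuffled gene names gave 54.3%, so probe sets of a gene disagreed less often than shuffled ones. Against empty vector, the CD mutant and the ED mutant, the KD mutant arrays differed in 20179, 20167 and 20123 probe sets, and Col1a2, Gpr15lg, Mfap5 and COX2 were each time among the 5 genes higher on the KD mutant arrays that the rule takes, with 1 probe set per named gene. On the side of the falls, it took Id2, Ppargc1a and Chchd10 in each of these comparisons, at -5.42, -4.96 and -4.87 against empty vector.

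Changes common to the 3 mutants were sought as probe sets changed the same way in each mutant against wild type. There were 0 in limma, which follows from the 0 probe sets changed in the CD mutant, so sharing among the 3 could not be measured. The mean of the 3 mutants differed from wild type in 16369 probe sets, 6471 higher and 9898 lower, and after centring each array on its median in 14582, of which 7822 were higher. Among genes whose arrays in all 3 mutants lay on the same side of both wild type arrays, with 1 probe set per named gene, the rises of this mean that the rule takes were Gpnmb, by 2.75, the vesicle transport gene Arf4, by 2.72, Ccng1 by 2.67, Sv2b by 2.64 and Copa by 2.09, and the falls were Chchd10, at -1.89, Rbp4 at -1.87, Tubb6 at -1.23, Ildr2 at -1.14 and the stress-induced cytokine gene Gdf15 at -1.09; Copa lay below the filter level in wild type, and Rbp4, Ildr2 and Gdf15 did on the KD mutant arrays. The group means of Arf4 were 5.4 ± 0.014 (SD, n = 2) in wild type, 5.51 ± 0.034 in the CD mutant, 5.55 ± 0.051 in the ED mutant and 13.28 ± 0.036 on the KD mutant arrays. With the KD mutant arrays left out, a comparison added after the data were seen, the mean of the CD and ED mutants differed from wild type in 0 probe sets (1273 at an unadjusted p under 0.05). By camera 4 lists shifted up in the mean of 3 mutants, TGF-beta targets, matrix remodelling enzymes, extracellular matrix and smooth muscle contractile genes (adjusted p = 2.25e-06 to 0.0138), and 0 with an estimated correlation (adjusted p = 0.357 to 0.38 with an estimated correlation) or with the KD mutant arrays left out.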

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

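The tests of the KD mutant arrays and of the poly-A controls described here were chosen after values were seen; for the poly-A controls 3 choices of probe sets were tried in turn, and the last is given.

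Affymetrix control probe sets for poly-A transcripts, which are outside the comparisons between groups, were brighter than on both empty vector arrays on both arrays of 2 groups, with means over 12 probe sets of 8.45 ± 0.06 (SD, n = 2) in the CD mutant and 8.12 ± 0.05 in the ED mutant against 7.79 ± 0.18, 0.66 and 0.32 higher. These controls are added to RNA before labelling, so a candidate explanation for both mutants' differences from empty vector is RNA input or labelling. It was examined for the ED mutant alone, and was left untested for the CD mutant and for the 8 probe sets shared by both. The 2 wild type arrays differed in these controls by 0.78, yet over the 119 probe sets with the largest mean differences between ED mutant and empty vector, taken by size alone (82 of them called), their median difference in the ED mutant's direction was 0.029 (interquartile range -0.087 to 0.13), against the ED mutant's own median change of 0.779. The earlier choices, the called probe sets and the 72 called without the wild type arrays, gave medians of 0.029 and 0.021 but depend on the arrays' own spread. In that pair, a larger gap in these controls thus came without most of the ED mutant's differences. Whether this gap and that of the ED mutant had the same source cannot be told from 1 pair of arrays, so RNA input or labelling stays open. An effect of the mutation and a difference between transfected lines were not tested and stay open, since each construct is represented by arrays whose labels name no separate lines.

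The KD mutant arrays differ from the other 8 in 20166 of 22502 probe sets against wild type, while no pair of groups without them differs in more than 119. Scaling of the arrays is argued against, because the highest Spearman correlation of a KD mutant array with another, which rescaling would leave near the rest, was 0.716 and the lowest among the other 8 was 0.989. A difference in expression alone, from the kinase domain mutation or from another rat cell type, stays open as the whole cause. Of 1122 genes with 2 or more brighter probe sets past 2-fold, 32.2% had probe sets in opposite directions, against 54.3% with shuffled gene names. One expression difference per gene might give few, although alternative transcript ends could add some. How many to expect was not measured on arrays of known rat cell types, so this share cannot decide the question. RNA of another organism on the 8 arrays, poorly matched by some rat probes, cannot be told apart from the rest: among genes with a probe set whose mean percentile was above 80 on both sets of arrays, 69 had another probe set under 40 on the 8 and above 80 on the KD mutant arrays and 0 had the reverse, but over all probe sets the split was 808 to 19, at which 1.6 reverse genes are expected (exact binomial test against that split, two-sided, p = 0.413). That test could not have favoured this explanation, because 0 is the lowest count possible and still gave that p-value. The split over all probe sets could itself come from such RNA, so no conclusion is drawn from the test. No probe sequences were used here, so the identity of the RNA on either set of arrays, and any effect of the mutation beneath the difference, stay open. The values of the wild type, CD and ED comparisons carry the same doubt.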

How the results depend on the processing

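The fit without the KD mutant arrays was chosen after the data were seen, and the other alternatives before; unless a cause is given, the cause was not tested. The number of arrays and the compression of dim signals limit the counts: 1 array left out leaves its group with 1, assumed to vary like the rest. Probe sets changed between wild type and empty vector (3) became 1 without a filter, 68 with an intensity trend and robust variance, 1 at adjusted p under 0.01, 1 with only the arrays compared, and 1 to 1 with an array left out. CD mutant against empty vector (25) became 8, 144, 3, 1 and 1 to 1 under the same settings and 43 without the KD mutant arrays. ED mutant against wild type (37) became 142 with the trend, 0 at adjusted p under 0.01, 0 with only the arrays compared and 0 to 1 with an array left out. ED mutant against empty vector (119) became 198 with the stricter filter, 179 after quantile normalization, 493 with the trend, 36 at adjusted p under 0.01, 63 with only the arrays compared, 19 to 37 with an array left out and 320 without the KD mutant arrays. ED against CD mutant (79) became 287 with the trend, 37 at adjusted p under 0.01, 38 with only the arrays compared, 12 to 31 with an array left out and 145 without the KD mutant arrays. Without the KD mutant arrays, the calls kept were 3 of 3 for wild type against empty vector, 35 of 37 for ED against wild type, 25 of 25 and 117 of 119 for CD and ED against empty vector, and 77 of 79 for ED against CD. Counted as genes, which are fewer, the KD mutant gave 10695 against wild type, 10716 against empty vector, 10725 against CD and 10669 against ED, and the mean of 3 mutants 8613. That mean (16369) became 6271 with a 1.5-fold minimum and 0 without the KD mutant arrays.

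Lists shifted against wild type in the KD mutant (8) became 4 with the stricter filter, 4 after quantile normalization, 0 with an estimated correlation, 30 with fry and 5 to 9 with an array left out, 5 without wild type replicate 1 or 2. In the ED mutant (0) they became 1 with the stricter filter, 1 with the trend, 2 with fry, 1 with the mean of all probe sets, 1 without the KD mutant arrays and 0 to 2 with an array left out, 2 without wild type replicate 2. The CD mutant (0) gave 1 with the trend, wild type against empty vector (0) gave 1 with fry, and the mean of 3 mutants (4) gave 8 without a filter, 0 with an estimated correlation, 28 with fry, 8 with the mean of all probe sets and 0 without the KD mutant arrays, where the extracellular matrix (adjusted p = 0.894) and matrix remodelling lists (adjusted p = 0.452) changed direction. Genes named for ED against wild type, tested under the alternatives that refit each gene, kept the call in 1 and lost it in 63 results with an array left out, lost it in 16 with only the arrays compared, and kept it in 103 and lost it in 8 under the other settings. In the other comparisons without the KD mutant the corresponding counts were 61 kept and 71 lost, 21 and 12, and 219 and 9. With the KD mutant 9 calls were lost. All of these were for the mean of 3 mutants with the KD mutant arrays left out, where no tested gene kept its call. None of these genes changed direction. Of the shifted lists, 156 results kept both, 30 lost the call and 2 changed direction.

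Replicate numbers are shared by the groups, but deviations of same-numbered arrays correlated over 0.1 in 1 of 10 pairs of groups (-0.029 to 0.143), so the numbers were not taken as pairing the samples. With a replicate block, 1 probe set changed between wild type and empty vector and 12 between CD mutant and empty vector; the other counts stayed within 1.5 times.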

Other observations

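The gene list shifts of the ED mutant against empty vector and the CD mutant were not among the comparisons of lists planned, and are values found after the data were seen. Against empty vector, the glycolysis and hypoxia list shifted up in the ED mutant, with a median change of 0.11 over 26 genes (camera adjusted p = 0.00174, and adjusted p = 0.517 with an estimated correlation). Its member Ndrg1, a stress-responsive gene, rose by 0.75 (adjusted p = 0.0336), and 2 members rose when adjusted over the list alone; Bnip3, at 0.53 (adjusted p = 0.0568), and Vegfa, at 0.35 (adjusted p = 0.242), did not pass over all probe sets. The interferon list shifted up by a median of 0.09 over 17 genes (adjusted p = 0.0312, and 0.517 with an estimated correlation), with the transcription factor gene Irf1 up by 0.70 (adjusted p = 0.0152) and the immunoproteasome subunit gene Psmb9 up by 0.70 (adjusted p = 0.0184), 2 members also over the list alone. Fry called neither the glycolysis nor the interferon list (adjusted p = 0.0937 and 0.0964), and called 1 list, the epithelial, up (adjusted p = 0.00937). Against the same empty vector arrays, the glycolysis list also leaned up with wild type and in the CD mutant, without passing (camera adjusted p = 0.129 and 0.0648). Cdh1 rose by 1.01 (adjusted p = 0.00364), while Tpm1, a tropomyosin gene, fell from 12.11 to 11.43 (adjusted p = 0.0336). Both wild type arrays and both CD mutant arrays had lower Id3 than both empty vector arrays, with group means of 8.77 and 8.78 against 9.59, without passing the test in either group (adjusted p = 0.126 and 0.0541).

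Against the CD mutant, the epithelial list lay higher in the ED mutant, with a median of 0.23 over 13 genes (camera adjusted p = 0.00775, and adjusted p = 0.362 with an estimated correlation). Krt19 was up by 0.72 (adjusted p = 0.0132) and Krt18 by 0.52 (adjusted p = 0.0482), and 4 members rose and 1 fell when adjusted over the list alone. The cholesterol synthesis list also lay higher, by a median of 0.13 over 19 genes (adjusted p = 0.035, and 0.518 with an estimated correlation), with 0 members past the test over all probe sets and 1 up over the list alone. Fry called the epithelial list (adjusted p = 0.00206) and the p53 and growth arrest list (adjusted p = 0.0127), both up, but not the cholesterol list (adjusted p = 0.198). Ccl20 and Ccl2 were higher in the ED than in the CD mutant by 0.96 (adjusted p = 0.00286) and 0.61 (adjusted p = 0.0338), and the neural cadherin gene Cdh2 changed by -0.61 (adjusted p = 0.027) and Myc by -0.59 (adjusted p = 0.0482).

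On the 8 arrays outside the KD mutant group, the median member of the epithelial list stood at percentile 83.8 of all probe sets and that of the smooth muscle contractile list at percentile 69.3, whereas on the KD mutant arrays they stood at percentiles 55.3 and 87.8. These levels are values of the arrays, and were set in no test.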
